A study of Arabidopsis thaliana with 32 samples.

How the data were processed

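RNA from Arabidopsis leaves was measured on 32 one-colour Agilent arrays, 4 for each of 8 groups: control, heat, drought, TuMV, and the 4 combinations of these stresses. Per the labels, treatments were randomised, controls were mock treated, and each biological replicate was a pool of leaves of several plants. Per the file headers, Feature Extraction 9.5.3.1 turned each scan into a processed signal for each spot, an intensity from which background had been subtracted and spatial trends removed, with no scaling between arrays. The authors' deposited values are in log2. For 43603 probes they matched the log2 processed signal minus each array's 75th percentile, centred on each probe's median over 31 arrays (median absolute difference 0.000912, 98.6% of values within 0.01). The tool behind these values is not given in the sources used here. They are blank for TuMV replicate 3, whose label says that it failed quality control, and this array was left out of every comparison. Scanner flags in the same files say whether a spot was well above background or saturated.

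Values were recomputed from the scanner files with R 4.3.3 and its packages limma 3.58.1 and data.table (version 1.17.8). The 43803 spots that are not controls make up 43603 probes, of which 37540 name 1 locus, 873 several and 5190 none, and only probes naming 1 locus stood for genes. The log2 processed signal minus the array's 75th percentile was used. A probe passed when it was well above background in at least 3 arrays of at least 1 group (31973 probes), and each gene took the passing probe with the highest mean, which gave 20875 genes, 5910 of them with several passing probes. Of the loci, 99.0% were found in the reference annotation. A choice of 1 probe can miss transcripts that the gene's other probes measure, and signal near background compresses differences, so genes with fewer than 2 of a group's arrays above background, with a group mean under the lowest level measured as such, or saturated in a group have only a bound on their fold. Of such genes no interaction is given except where its sign turned, but counts and list medians of interactions hold them.

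A single linear model over the 8 groups and 31 arrays was fitted with limma (lmFit and eBayes) and tested with 14 contrasts: 7 stresses against control, TuMV within drought, within heat and within both, 3 pairwise interactions (departure of a combined stress from the sum of its parts on the log2 scale) and the 3-way interaction. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes of a contrast, with 0.05 as threshold. Values are log2 differences ± standard error. The number of arrays limits the precision. Gene lists were 22, matched by locus, of which 21 had enough measured members to test. Camera of limma was run with a preset correlation between genes of 0.01 and again with an estimated correlation, and p was adjusted over all 294 tests. Members past the test were counted over all genes and adjusted over the list alone. Where no count adjusted over the list alone is given, it equals that over all genes, and lists printed with 1 adjusted p below 0.05 passed with an estimated correlation too.

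The gene lists, the contrasts, the alternatives and the rule for naming genes were set before the data were examined. The rule takes, for each comparison, the 4 greatest rises and 4 greatest falls among genes with a symbol that passed and whose arrays did not overlap, up to 4 members of each list that passed, and 15 genes always considered, HSP101, HSFA2, AT1G53540 (HSP17.6C), DREB2A, RD29B, RAB18, PR1, PR2, PR5, ICS1, WRKY70, PAD4, AGO2, LHCB1.1 and RBCS1A. From this set, the genes printed as examples were mostly those whose call held under the alternatives. Flower genes and genes of endoplasmic reticulum bodies lie outside the rule and were named after their values were seen.

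The scan dates and slides in the file headers give 2 dates, each with every group, and 8 slides of 4 arrays with 2 groups each. Only heat, heat by drought and the 3-way interaction can be estimated within slides, and every other contrast compares arrays on different slides. Counts and list medians were recomputed with scan date as a block, within each date, and with slide as a block. Between the dates 7148 genes differed, 90 of them at least 2-fold. The correlation of arrays within a slide was 0.233. Replicate numbers were checked for pairing: after removal of group means, arrays with the same number in different groups had a median correlation of 0.119 (57 of 105 pairs over 0.1), those of the same date with another number 0.130 (64 of 105) and those of different dates −0.119 (6 of 210). Every pair was over 0.1 for 5 of 28 pairs of groups: heat with drought, with TuMV, with drought with heat and with TuMV with heat, and drought with drought with heat. Only heat and TuMV with heat among these form a contrast of 2 groups, and no interaction had it for all its groups, so no replicate block was used except as an alternative.

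Alternatives were quantile scaling, normexp background correction (offset 50) on the raw spot and background intensity, the deposited values, no filter, a filter asking for every array of a group, the mean of a gene's probes, every probe by itself, only the groups compared, scan date, slide or replicate number as a block, TuMV replicate 3 included, a 2-fold minimum, and leaving out each array. Arrays simulated from the fitted means and spread tested the recovery of known changes. Overlaps between stresses that share controls were set beside n1 × n2 / N, 20 simulations with no effect and counts with the controls divided between the stresses. Figures were drawn with matplotlib 3.10.9.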

Results

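The series holds 32 Agilent arrays of Arabidopsis Columbia leaves, 4 for each of 8 groups. Plants met turnip mosaic virus (TuMV), drought or heat alone, each pair of these, all 3 together, or none. Leaves were taken at 34 days of age from plants that had carried the virus for 13 days, mild drought for 5 days or heat for 3 days. By the labels each array is a biological replicate, a pool of leaves of several plants. TuMV replicate 3, labelled as failing quality control, was left out, so TuMV alone has n = 3 and every other group n = 4. Of 43603 probes, 31973 were above background in at least 3 arrays of a group, and 20875 genes were tested. The 75th percentile of signal ran from 1133 to 2389 (median 1713). Of the probes, 63.2 to 77.8% were above background, with group means from 66.8% in control to 72.9% in heat. In arrays simulated without slide or date effects, 200 genes were altered. Of 2-fold changes, 91.2% were recovered in a contrast like heat, 81.2% for TuMV, 73.2% for heat by drought and 42.9% for the 3-way interaction. Of the calls, 4.63 to 5.18% fell on unchanged genes. These rates need not hold for real calls.

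On the TAIR10.1 assembly the protein-coding genes named most below lie as follows, from the first to the last base of the gene: LHCB1.1 (AT1G29920) on chromosome 1 from 10474656 to 10475969, HSP101 (AT1G74310) on chromosome 1 from 27936508 to 27940369, and PR1 (AT2G14610) on chromosome 2 from 6241640 to 6242541. HSFA2 (AT2G26150) lies on chromosome 2 from 11135624 to 11137792, PYK10 (AT3G09260) on chromosome 3 from 2840477 to 2843781 and RD29B (AT5G52300) on chromosome 5 from 21237021 to 21239531. The first 4 principal components of the 31 arrays held 51.6, 12.3, 7.29 and 5.58% of the variance. Heat alone changed 12329 genes, drought 4882 and TuMV 3295, and the triple stress 13884 (adjusted p below 0.05). Of 294 tests of a gene list in a contrast, 115 passed, 31 also with an estimated correlation among genes (those given here with 1 adjusted p). Median, mean and test differed in sign in 39 of the 294, none of them among those that passed. Where a fold is given as a bound ("at least"), fewer than 2 of 1 group's arrays were above background, their mean lay below the level at which a spot counts as measured, or they were saturated, and the fold is taken to that level.

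**Figure D1:**
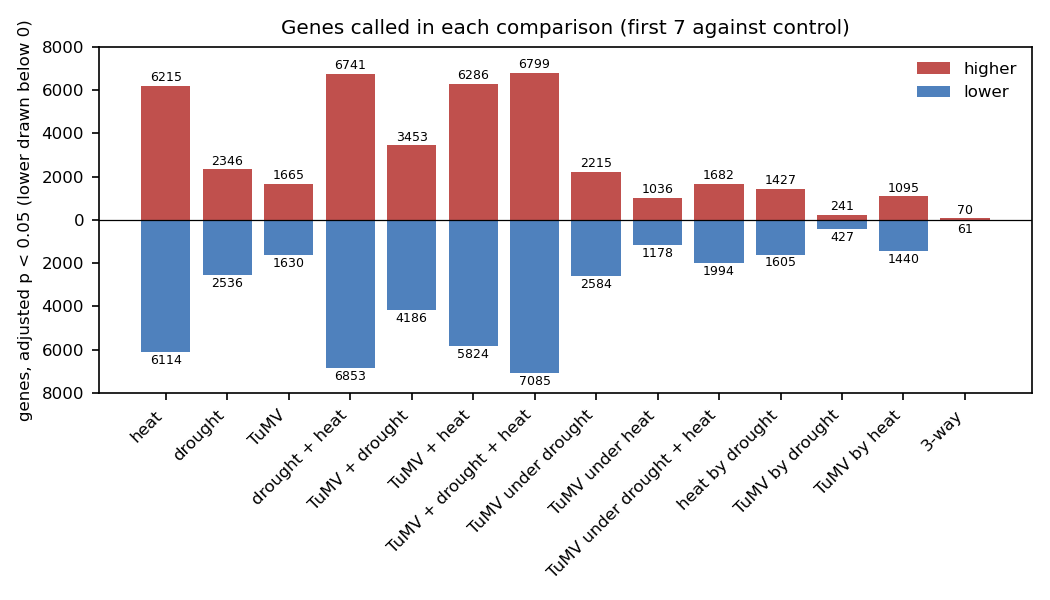
Number of genes higher (bars above 0) and lower (bars below 0) at adjusted p below 0.05 in each of the 14 contrasts, the first 7 against control, with the number at each bar. Heat gave 6215 genes higher and 6114 lower, TuMV 1665 and 1630, and the 3-way interaction 70 and 61.

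Heat for 3 days lowered transcripts of the light-harvesting antenna and raised those of chaperones. Among photosynthesis genes, 45 of 46 fell and 0 rose, median −0.77 (adjusted p = 5.97e-20). LHCB2.4 (AT3G27690), LHCB1.1, LHCB2.1 (AT2G05100) and LHCB1.4 (AT2G34430), which encode chlorophyll-binding proteins of the photosystem II antenna, fell by log2 3.54 ± 0.17, 3.36 ± 0.12, 3.32 ± 0.12 and 2.18 ± 0.11. Of the heat shock proteins and chaperones, 20 of 23 rose and 1 fell, median 2.53 (adjusted p = 1.53e-09, and adjusted p = 0.167 with an estimated correlation). The median was 2.16 with 8 members at their bound. AT1G53540, which encodes a class I small heat shock protein, rose at least 52.0-fold, HSP23.6-MITO (AT4G25200) of mitochondria at least 31.3-fold and ATHSP22.0 (AT4G10250) at least 14.7-fold. HOP3 (AT4G12400), a cochaperone between HSP70 and HSP90, rose by 5.95 ± 0.18. HSP101, the disaggregase needed for acquired thermotolerance, rose by 1.03 ± 0.33 (adjusted p = 0.0101, call lost with normexp), and the regulator HSFA2 was at 0.05 ± 0.52 (adjusted p = 0.947).

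Under heat PYK10, a beta-glucosidase of the endoplasmic reticulum bodies, rose at least 138-fold (6 other passing probes higher). DR4 (AT1G73330) rose at least 31.5-fold. GolS3 (AT1G09350), which encodes a galactinol synthase, fell by 6.28 ± 0.62, MEE3 (AT2G21650) by 3.87 ± 0.21, the defensin PDF1.2A (AT5G44420) at least 11.7-fold and MIR169m (AT3G26818) at least 9.10-fold. In the endoplasmic reticulum folding list, 13 of 16 rose and 1 fell, median 1.05 (adjusted p = 6.29e-06, and adjusted p = 0.0730 with an estimated correlation). ERDJ3A (AT3G08970), ERDJ3B (AT3G62600) and the lectin chaperone CNX1 (AT5G61790) rose by 1.52 ± 0.27, 1.24 ± 0.12 and 1.23 ± 0.10. For starch, 10 of 13 fell and 0 rose, median −0.88 (adjusted p = 4.39e-05). Among them were the glucan phosphorylases PHS2 (AT3G46970, −1.52 ± 0.08) and PHS1 (AT3G29320, −1.44 ± 0.06), DPE2 (AT2G40840, −1.22 ± 0.15) and the glucan water dikinase SEX1 (AT1G10760, −1.14 ± 0.12).

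Of flavonoid genes, 10 of 14 rose and 1 fell, median 1.01 (adjusted p = 0.00396, and adjusted p = 0.272 with an estimated correlation). Chalcone synthase, CHS (AT5G13930), rose by 3.58 ± 0.32 and F3H (AT3G51240) by 2.06 ± 0.21. Of the resistance genes, 18 of 27 rose and 2 fell, median 0.31 (adjusted p = 0.0156, and adjusted p = 0.422 with an estimated correlation). Among them were ADR1-L2 (AT5G04720, 1.27 ± 0.21) and WRR4 (AT1G56510, 1.23 ± 0.22). Of TIR-NBS-LRR genes, 33 of 65 rose and 9 fell, median 0.33 (adjusted p = 0.0248, and adjusted p = 0.553 with an estimated correlation), lost with quantile scaling. AT1G72900 was at 2.87 ± 0.35. For cytosolic ribosomal proteins, 81 of 185 fell and 31 rose, median −0.18 (adjusted p = 0.0437, and adjusted p = 0.803 with an estimated correlation), but at 0.04 with quantile scaling. The call was lost without control replicate 2 (−0.17), without heat replicate 1 (−0.16), without control replicate 3 (−0.16), without heat replicate 3 (−0.16), with normexp, with quantile scaling and with no filter. AT2G24110 rose by 1.81 ± 0.10. PR5 (AT1G75040) fell by 1.46 ± 0.37, PAD4 (AT3G52430) rose by 1.03 ± 0.28 and RBCS1A (AT1G67090), a small subunit of Rubisco, fell by 0.38 ± 0.09, although it stood at 0.15 with quantile scaling. Not passing were DREB2A (AT5G05410, −0.53 ± 0.55), RD29B (−0.06 ± 0.31), RAB18 (AT5G66400, −0.15 ± 0.12), PR2 (AT3G57260, 0.97 ± 0.54), ICS1 (AT1G74710, 0.09 ± 0.20), WRKY70 (AT3G56400, 0.58 ± 0.27) and AGO2 (AT1G31280, −0.20 ± 0.19). PR1 was not above background (adjusted p = 0.979). Of all 20875 genes, 52.6% had arrays of heat and control that did not overlap (2.86% by chance for a gene without change). With scan date as a block 13181 genes were called and with slide as a random block 13125, within the 2 scan dates 10647 and 10541, and all 8 lists called kept their sign within both dates (photosynthesis −0.81 and −0.73, chaperones 2.70 and 2.49).

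Drought for 5 days lowered ribosomal protein and aquaporin transcripts and raised defence genes. Of cytosolic ribosomal proteins, 84 of 185 fell and 1 rose (105 and 1 adjusted over the list alone), median −0.26 (adjusted p = 8.15e-16, and adjusted p = 0.148 with an estimated correlation). AT2G41840 and AT3G09630 fell by 0.66 ± 0.14 and 0.56 ± 0.09. Of the aquaporins, the water channels of the plasma and vacuolar membranes, 7 of 16 fell and 0 rose (10 and 0 adjusted over the list alone), median −0.35 (adjusted p = 7.82e-04, and adjusted p = 0.251 with an estimated correlation). PIP1;2 (AT2G45960) was at −0.53 ± 0.10 and PIP1;1 (AT3G61430) at −0.44 ± 0.09. Among genes of salicylic acid and basal defence, 15 of 37 rose and 0 fell (16 and 0 adjusted over the list alone), median 0.71 (adjusted p = 5.10e-06, and adjusted p = 0.413 with an estimated correlation). Among them were WRKY38 (AT5G22570, 1.74 ± 0.23), NIMIN1 (AT1G02450, 1.3 ± 0.23) and WRKY70 (0.99 ± 0.27). TIR-NBS-LRR genes, which encode a class of immune receptors, rose in part: 19 of 65 rose and 0 fell (21 and 0 adjusted over the list alone), median 0.32 (adjusted p = 1.62e-06, and adjusted p = 0.123 with an estimated correlation). AT1G31540 was at 1.07 ± 0.15. For resistance genes, 7 of 27 rose and 1 fell (12 and 2 adjusted over the list alone), median 0.22 (adjusted p = 0.00174, and adjusted p = 0.267 with an estimated correlation). Among them were RPS2 (AT4G26090, 0.76 ± 0.17) and CHS1 (AT1G17610, 0.56 ± 0.11).

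Under drought EXO (AT4G08950, 4.31 ± 0.49) and its relative PHI-1 (AT1G35140, 4.18 ± 0.75), JAZ7 (AT2G34600), a jasmonate repressor (at least 11.1-fold), and RBL7 (AT4G23070) (at least 7.04-fold) rose. PDF1.2A was at least 9.24-fold lower. DREB1A (AT4G25480), a regulator of the cold response, and MYBL2 (AT1G71030), a repressor of anthocyanin synthesis, fell by 2.97 ± 0.46 and 2.08 ± 0.19. The calls for JAZ7, RBL7 and PDF1.2A were lost with normexp. Jasmonate and ethylene genes gave 8 of 30 higher and 3 lower (11 and 3 adjusted over the list alone), median 0.46 (adjusted p = 0.0202, and adjusted p = 0.709 with an estimated correlation). The list's call was lost without control replicate 3 (0.32), without control replicate 4 (0.45) and without drought replicate 4 (0.29), with medians in parentheses. HSFA2 rose by 2.09 ± 0.52 and LHCB1.1 fell by 0.64 ± 0.12, and the photosynthesis list was at a median of 0.05 (adjusted p = 0.711). For the drought and abscisic acid list, 12 of 39 rose and 4 fell (12 and 5 adjusted over the list alone), median 0.19 (adjusted p = 0.0513). Neither RD29B (0.70 ± 0.31) nor RAB18 (−0.20 ± 0.12), both markers of abscisic acid, nor DREB2A (0.00 ± 0.55) passed. RAB18 did pass as higher, at 0.38, when its probes were averaged (adjusted p = 0.0277), 2 of its 3 other probes being higher. Also not passing were HSP101 (0.53 ± 0.33), PR2 (0.80 ± 0.54), PR5 (−0.34 ± 0.37), ICS1 (−0.45 ± 0.20), PAD4 (0.49 ± 0.28), AGO2 (0.29 ± 0.19) and RBCS1A (0.11 ± 0.09). PR1 (adjusted p = 0.758) and AT1G53540 were not above background. Arrays did not overlap in 22.3% of all genes (2.86% by chance). The total was 6223 with scan date as a block, 3322 with slide as a random block (lower genes 2536 to 1659), and 1837 and 3162 within the scan dates. All 6 lists called kept their sign within both dates (ribosomal proteins −0.27 and −0.25, salicylic acid 0.58 and 0.73).

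TuMV alone raised genes of defence, of jasmonate and of protein folding in the endoplasmic reticulum, with n = 3 infected arrays. Of salicylic acid and basal defence genes, 21 of 37 rose and 0 fell (26 and 0 adjusted over the list alone), median 0.85 (adjusted p = 8.80e-14, and adjusted p = 0.135 with an estimated correlation). WRKY18 (AT4G31800), a regulator of defence, rose by 3.22 ± 0.51, and PR2, a beta-1,3-glucanase, by 2.52 ± 0.58. PR1 was at least 4.03-fold higher (adjusted p = 0.0349), and at least 9.86-fold without TuMV replicate 4, where it was not above background. Its call was lost without control replicate 2, 3 or 4 (at least 4.54, 3.41 and 4.68-fold), without TuMV replicate 1 or 2 (at least 2.28-fold in both) and with normexp, no filter, slide as a random block or only the 2 groups. PR5 rose by 1.4 ± 0.40, lost without TuMV replicate 2 (0.98) and with slide as a random block. Of endoplasmic reticulum folding genes, 11 of 16 rose and 0 fell (12 and 0 adjusted over the list alone), median 0.51 (adjusted p = 2.25e-11). The chaperone BIP2 (AT5G42020) rose by 0.88 ± 0.12 and BZIP60 (AT1G42990) by 0.76 ± 0.19. Among jasmonate and ethylene genes, 14 of 30 rose and 0 fell (16 and 0 adjusted over the list alone), median 0.99 (adjusted p = 6.47e-09, and adjusted p = 0.234 with an estimated correlation). Examples were JAZ7 (at least 24.6-fold), the biosynthetic AOC3 (AT3G25780) (at least 15.3-fold), TAT3 (AT2G24850, 4.07 ± 0.74) and, outside the list, CYP94B3 (AT3G48520), which oxidises jasmonoyl-isoleucine (4.96 ± 1.31). ABR1 (AT5G64750), an ethylene response factor, rose at least 13.4-fold (call lost with normexp).

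Under TuMV CIPK20 (AT5G45820), a protein kinase (−2.96 ± 0.22), and DREB1A (−2.78 ± 0.50) fell. In the circadian clock list, 9 of 14 fell and 1 rose, median −0.34 (adjusted p = 2.33e-04). Among them were the pseudo-response regulators PRR5 (AT5G24470, −1.53 ± 0.19) and PRR7 (AT5G02810, −1.03 ± 0.11). For photosynthesis, 11 of 46 fell and 0 rose, median −0.15 (adjusted p = 8.44e-07, and adjusted p = 0.329 with an estimated correlation), lost with quantile scaling. LHCB2.1 (−1.98 ± 0.13) and LHCB2.4 (−1.2 ± 0.18) were among them. TIR-NBS-LRR genes gave 15 of 65 higher and 0 lower (19 and 0 adjusted over the list alone), median 0.29 (adjusted p = 9.79e-08, and adjusted p = 0.0712 with an estimated correlation). AT5G41750 rose by 1.90 ± 0.52. Resistance genes gave 9 of 27 higher and 0 lower (11 and 0 adjusted over the list alone), median 0.20 (adjusted p = 4.09e-04, and adjusted p = 0.199 with an estimated correlation), WRR4 (1.06 ± 0.24) and RPS2 (0.73 ± 0.18) among them. RNA silencing genes were at −0.04 (adjusted p = 0.980) and ribosomal proteins at −0.03 (adjusted p = 0.638). HSFA2 rose by 2.01 ± 0.56, lost without TuMV replicate 2 (1.75), with normexp and with slide as a random block. Not passing were HSP101 (0.47 ± 0.36), AT1G53540 (adjusted p = 0.122), DREB2A (−0.28 ± 0.59), RD29B (0.07 ± 0.33), RAB18 (−0.35 ± 0.13), ICS1 (0.02 ± 0.22), WRKY70 (0.15 ± 0.29), PAD4 (0.73 ± 0.30), AGO2 (0.50 ± 0.21) and RBCS1A (−0.12 ± 0.10). Without TuMV replicate 2, 1024 genes were lower. Arrays did not overlap in 28.9% of all genes (5.71% by chance with 4 and 3 arrays). The total was 4271 with scan date as a block, 2309 with slide as a random block (lower genes 1630 to 1080), and 2411 and 1173 within the scan dates. All 10 lists called kept their sign within both dates (salicylic acid 1.03 and 0.66, endoplasmic reticulum 0.51 and 0.57).

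**Figure D2:**
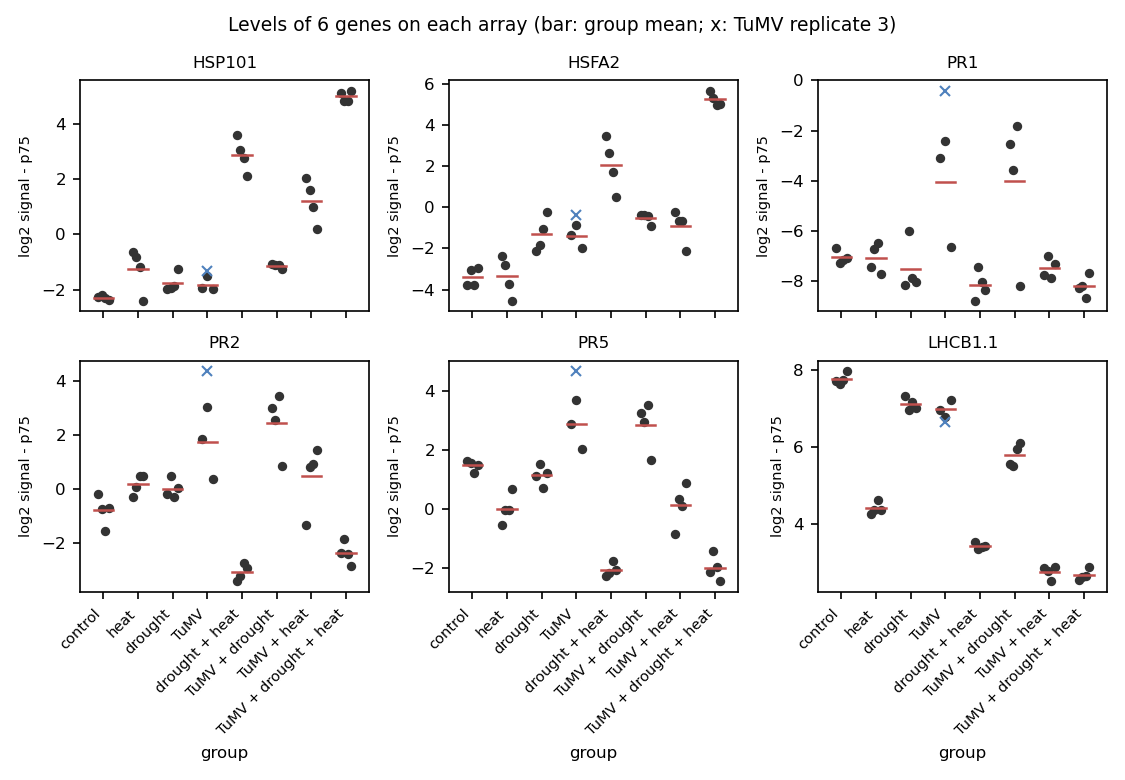
Level of HSP101, HSFA2, PR1, PR2, PR5 and LHCB1.1 (log2 signal minus the array's 75th percentile) in each array by group, with dots for arrays, bars for group means and a cross for TuMV replicate 3, which was left out. The mean of LHCB1.1 was 7.76 in control, 4.40 in heat and 2.68 in the triple stress.

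With drought and heat together, chaperone genes rose and antenna genes fell. Of heat shock proteins and chaperones, 23 of 23 rose and 0 fell, median 5.70 (adjusted p = 2.74e-17), or 5.41 with 8 members at their bound. HSP23.6-MITO rose at least 562-fold, AT1G53540 at least 397-fold, ATHSP22.0 at least 138-fold and HSP17.6II (AT5G12020) at least 78.9-fold. HSP101 rose by 5.16 ± 0.33 and HSFA2 by 5.48 ± 0.52. Photosynthesis genes gave 46 of 46 lower and 0 higher, median −1.0 (adjusted p = 1.56e-19). LHCB1.1 was at −4.34 ± 0.12 and LHCB2.4 at −4.18 ± 0.17. PYK10 rose at least 229-fold and SWEET15 (AT5G13170), a sugar transporter, at least 89.5-fold. GolS3 (−6.66 ± 0.62), MEE3 (at least 62.7-fold) and the glutathione transferases GSTF7 (AT1G02920) (at least 33.4-fold) and GSTF2 (AT4G02520, −5.69 ± 0.29) fell. For starch, 9 of 13 fell and 1 rose, median −0.61 (adjusted p = 0.00134, and adjusted p = 0.131 with an estimated correlation). PHS1 fell by 1.62 ± 0.06, while GBSS1 (AT1G32900), which makes amylose, rose by 2.12 ± 0.34. For flavonoids, 10 of 14 rose and 1 fell, median 0.92 (adjusted p = 0.0117, and adjusted p = 0.357 with an estimated correlation). CHS (4.07 ± 0.32) and the regulator PAP1 (AT1G56650, 2.16 ± 0.30) rose.

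RNA silencing genes rose under drought with heat: 13 of 19 rose and 1 fell, median 0.39 (adjusted p = 0.0201, and adjusted p = 0.208 with an estimated correlation). Examples were AGO3 (AT1G31290, 2.25 ± 0.28), the double-stranded RNA binding HYL1 (AT1G09700, 0.81 ± 0.13) and DCL3 (AT3G43920, 0.64 ± 0.07). TIR-NBS-LRR genes gave 33 of 65 higher and 8 lower, median 0.39 (adjusted p = 0.00280, and adjusted p = 0.374 with an estimated correlation), or 0.27 with members at their bound. AT1G72900 was at 3.23 ± 0.35. For aquaporins, 12 of 16 fell and 0 rose (12 and 2 adjusted over the list alone), median −0.56 (adjusted p = 0.0120, and adjusted p = 0.413 with an estimated correlation), lost with quantile scaling. PIP1;1 was at −0.94 ± 0.09. Endoplasmic reticulum folding gave 10 of 16 higher and 2 lower, median 0.43 (adjusted p = 0.0466, and adjusted p = 0.521 with an estimated correlation), a call lost without control replicate 1 (0.38), without drought with heat replicate 1 (0.37), without control replicate 3 (0.43), with a stricter filter, with scan date as a block, with replicate number as a block and with only the groups compared. ERDJ3A rose by 3.36 ± 0.27 and BIP3 (AT1G09080) was at least 3.52-fold lower (lost with normexp). The abscisic acid marker RD29B rose by 1.62 ± 0.31 and PAD4 by 1.12 ± 0.28, while PR2, PR5 and ICS1, which makes the precursor of salicylic acid, fell by 2.28 ± 0.54, 3.55 ± 0.37 and 0.86 ± 0.20. The salicylic acid list was at 0.09 (adjusted p = 0.985). RBCS1A fell by 0.40 ± 0.09 but was at 0.26 with quantile scaling. DREB2A (1.21 ± 0.55), WRKY70 (0.42 ± 0.27) and RAB18 (0.00 ± 0.12) did not pass, RAB18 being at 0.39 with quantile scaling and 0.99 with probes averaged (all 3 other probes higher), and PR1 was not above background in either group. Of all genes, 60.0% had arrays that did not overlap (2.86% by chance). The total was 13594, and 14376 with scan date as a block, 12643 with slide as a random block, and 11884 and 12077 within the scan dates. All 9 lists called kept their sign within both dates (chaperones 6.01 and 5.41).

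With TuMV and drought together, jasmonate, defence and endoplasmic reticulum genes rose, and ribosomal protein, antenna and clock genes fell. Of jasmonate and ethylene genes, 23 of 30 rose and 3 fell, median 1.63 (adjusted p = 5.39e-08, and adjusted p = 0.267 with an estimated correlation). Among them were TAT3 (5.40 ± 0.68), JAZ7 (at least 24.1-fold), AOC3 (at least 19.1-fold) and JAZ10 (AT5G13220, 4.61 ± 0.69). CYP94B1 (AT5G63450) and CYP94B3, which oxidise jasmonoyl-isoleucine, rose at least 83.7-fold and by 6.29 ± 1.21, and the ethylene response factors RAP2.6 (AT1G43160) and ABR1 at least 20-fold and at least 24.3-fold. Of salicylic acid and basal defence genes, 26 of 37 rose and 0 fell (30 and 0 adjusted over the list alone), median 1.21 (adjusted p = 7.49e-12, and adjusted p = 0.173 with an estimated correlation). Examples were GRX480 (AT1G28480, 4.11 ± 0.56), DLO1 (AT4G10500), which hydroxylates salicylic acid (3.54 ± 0.66), PR2 (3.24 ± 0.54), PR5 (1.37 ± 0.37) and PAD4 (1.2 ± 0.28). PR1 was at least 4.07-fold higher (adjusted p = 0.010), a call lost without TuMV with drought replicate 3 (at least 2.44-fold), with normexp and with only the 2 groups. It was not above background in replicate 4, without which it was at least 10.7-fold higher. In endoplasmic reticulum folding, 14 of 16 rose and 0 fell (15 and 0 adjusted over the list alone), median 0.79 (adjusted p = 7.37e-12). Among them were BIP3 (3.29 ± 0.62), ERDJ3A (1.89 ± 0.27) and BIP2 (1.24 ± 0.11). Ribosomal proteins gave 123 of 185 lower and 1 higher (138 and 1 adjusted over the list alone), median −0.32 (adjusted p = 2.77e-15, and adjusted p = 0.157 with an estimated correlation). AT2G20450 was at −0.68 ± 0.09. For photosynthesis, 37 of 46 fell and 0 rose (39 and 0 adjusted over the list alone), median −0.31 (adjusted p = 5.07e-13, and adjusted p = 0.123 with an estimated correlation). LHCB2.1 was at −2.72 ± 0.12 and LHCB1.1 at −1.98 ± 0.12.

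The clock list gave 9 of 14 lower and 2 higher, median −0.49 (adjusted p = 5.05e-04), PRR5, PRR7 and GI (AT1G22770) falling by 2.53 ± 0.17, 1.69 ± 0.10 and 1.63 ± 0.24. CIPK20, DREB1A and MYBL2 fell (−4.99 ± 0.21, −3.84 ± 0.46 and −3.14 ± 0.19), and PDF1.2A was at least 9.93-fold lower (call lost with normexp). Chaperones gave 11 of 23 higher and 1 lower, median 0.32 (adjusted p = 6.28e-04, and adjusted p = 0.50 with an estimated correlation). HSP70 (AT3G12580) was at 2.85 ± 0.28. HSFA2 rose by 2.87 ± 0.52, HSP101 by 1.16 ± 0.33 (lost with normexp) and AT1G53540 at least 2.94-fold (lost with normexp). Flavonoids gave 10 of 14 higher and 0 lower (11 and 0 adjusted over the list alone), median 0.84 (adjusted p = 2.33e-05, and adjusted p = 0.0854 with an estimated correlation). CHS was at 1.96 ± 0.32. TIR-NBS-LRR genes gave 33 of 65 higher and 2 lower (35 and 2 adjusted over the list alone), median 0.42 (adjusted p = 1.04e-07, and adjusted p = 0.0712 with an estimated correlation). AT5G41750 was at 2.17 ± 0.48. Aquaporins gave 11 of 16 lower and 0 higher (12 and 0 adjusted over the list alone), median −0.50 (adjusted p = 2.79e-04, and adjusted p = 0.195 with an estimated correlation). PIP2;6 (AT2G39010) was at −0.67 ± 0.13. Glucosinolates and camalexin gave 7 of 23 higher and 1 lower (7 and 2 adjusted over the list alone), median 0.24 (adjusted p = 0.0301, and adjusted p = 0.690 with an estimated correlation). PAD3 (AT3G26830), the last step to camalexin, was at 3.21 ± 0.67. The list's call was lost without control replicate 3 (0.11), without control replicate 4 (0.23) and without TuMV with drought replicate 3 (0.14). AGO2 rose by 0.92 ± 0.19 and RAB18 fell by 0.76 ± 0.12. RD29B (0.44 ± 0.31) and WRKY70 (0.60 ± 0.27) did not pass. Arrays did not overlap in 34.0% of all genes (2.86% by chance). There were 7639 calls in total. Scan date as a block gave 8837, slide as a random block 6125, and the scan dates alone 6171 and 4565. All 12 lists called kept their sign within both dates (jasmonate 0.77 and 1.85).

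**Figure D3:**
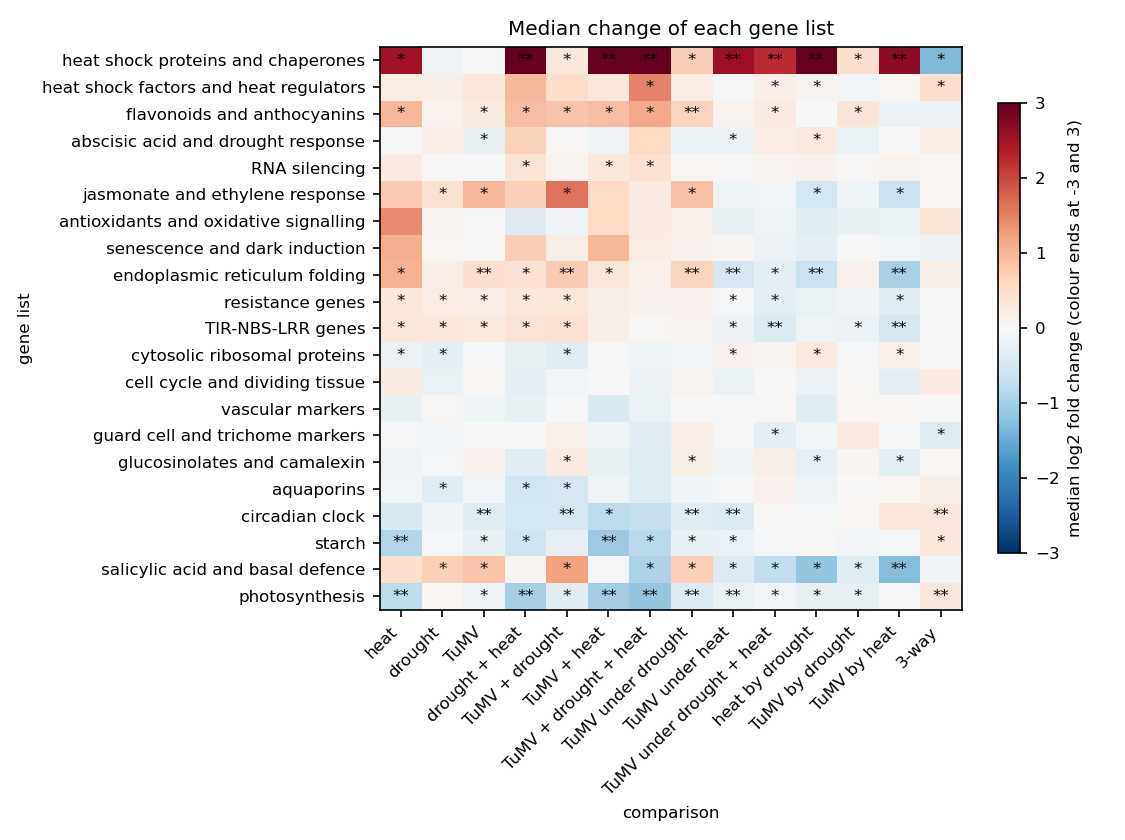
Median log2 change of 21 gene lists (vertical) in 14 contrasts (horizontal), red for higher and blue for lower, with colours ending at −3 and 3. A single star marks adjusted p below 0.05 and a double star adjusted p below 0.05 also with an estimated correlation, as for chaperones under TuMV with heat (median 5.97).

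With TuMV and heat together, antenna genes fell and chaperone genes rose, and defence lists did not pass. For photosynthesis, 46 of 46 fell and 0 rose, median −1.03 (adjusted p = 1.65e-25). Examples were LHCB1.1 (−5.01 ± 0.12), LHCB2.4 (−4.70 ± 0.17) and LHCB2.1 (−4.25 ± 0.12). Of heat shock proteins and chaperones, 23 of 23 rose and 0 fell, median 5.97 (adjusted p = 1.56e-19), or 5.95 with 8 members at their bound. AT1G53540 rose at least 1446-fold, HSP23.6-MITO at least 400-fold, ATHSP22.0 at least 249-fold and HSP17.4 (AT3G46230) at least 118-fold. HSP101 rose by 3.49 ± 0.33 and HSFA2 by 2.49 ± 0.52. GolS3 fell by 6.17 ± 0.62, and PDF1.2A was at least 13.6-fold lower (lost with normexp). For starch, 11 of 13 fell and 0 rose (11 and 1 adjusted over the list alone), median −1.08 (adjusted p = 5.76e-06). PHS1 was at −1.88 ± 0.06. For flavonoids, 10 of 14 rose and 1 fell, median 0.92 (adjusted p = 0.00306, and adjusted p = 0.265 with an estimated correlation). CHS was at 4.27 ± 0.32. RNA silencing gave 10 of 19 higher and 0 lower, median 0.31 (adjusted p = 0.0288, and adjusted p = 0.256 with an estimated correlation), lost with quantile scaling. AGO3 was at 2.23 ± 0.28.

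Under TuMV with heat the clock list gave 9 of 14 lower and 4 higher, median −0.76 (adjusted p = 0.0373, and adjusted p = 0.270 with an estimated correlation), lost with quantile scaling, with no filter, with probes averaged and with only the groups compared. PRR5 was at −2.16 ± 0.17 and the morning gene RVE1 (AT5G17300) at 2.59 ± 0.28, while RVE8 (AT3G09600) was at least 2.50-fold higher. Endoplasmic reticulum folding gave 10 of 16 higher and 1 lower, median 0.35 (adjusted p = 0.0256, and adjusted p = 0.443 with an estimated correlation), lost with normexp. ERDJ3A was at 1.88 ± 0.27. The salicylic acid list was at −0.06 (adjusted p = 0.824), jasmonate at 0.57 (adjusted p = 0.915), ribosomal proteins at −0.06 (adjusted p = 0.830) and aquaporins at −0.12 (adjusted p = 0.730). With quantile scaling the ribosomal median was 0.24 and the aquaporin median 0.40. PR5 fell by 1.36 ± 0.37, RAB18 by 0.47 ± 0.12 (lost with quantile scaling) and RBCS1A by 0.53 ± 0.09 (0.16 with quantile scaling). WRKY70 (−0.55 ± 0.27), PAD4 (0.56 ± 0.28) and AGO2 (0.44 ± 0.19) did not pass, and PR1 was not above background in either group. Arrays did not overlap in 55.0% of all genes (2.86% by chance). The total was 12110, and 13026 with scan date as a block, 10991 with slide as a random block, and 10197 and 10181 within the scan dates. All 7 lists called kept their sign within both dates (chaperones 6.24 and 5.94). Normexp moved the median of all genes by 0.157.

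The triple stress raised chaperone genes and lowered antenna and salicylic acid genes. Of heat shock proteins and chaperones, 23 of 23 rose and 0 fell, median 8.50 (adjusted p = 1.36e-20), or 7.98 with 8 members at their bound. AT1G53540 rose at least 3796-fold, HSP23.6-MITO at least 2525-fold, ATHSP22.0 at least 1339-fold, HSP17.6A (AT5G12030) at least 601-fold and HSP17.6II at least 478-fold, and HSP101 by 7.27 ± 0.33. Of heat shock factors and regulators, 8 of 13 rose and 2 fell, median 1.48 (adjusted p = 0.0202, and adjusted p = 0.190 with an estimated correlation). Among them were HSFA2 (8.66 ± 0.52), HSFA7A (AT3G51910, 6.27 ± 0.24) and the coactivator MBF1C (AT3G24500, 5.25 ± 0.40). Photosynthesis gave 45 of 46 lower and 0 higher, median −1.15 (adjusted p = 5.97e-20). LHCB1.1 was at −5.08 ± 0.12. Of salicylic acid and basal defence genes, 22 of 37 fell and 3 rose, median −0.92 (adjusted p = 0.00291, and adjusted p = 0.650 with an estimated correlation): WRKY38 (−4.03 ± 0.23), PR5 (−3.46 ± 0.37), WRKY54 (AT2G40750, −2.58 ± 0.18), WRKY70 (−1.85 ± 0.27), PR2 (−1.58 ± 0.54) and ICS1 (−0.87 ± 0.20) fell. RNA silencing gave 14 of 19 higher and 1 lower, median 0.43 (adjusted p = 0.00344, and adjusted p = 0.107 with an estimated correlation). AGO2, an Argonaute of antiviral silencing, was at 1.81 ± 0.19.

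Under the triple stress GolS3 (−7.92 ± 0.62), MEE3 (at least 53.5-fold), GSTF2 (−5.45 ± 0.29) and GSTF7 (at least 29.5-fold) fell. Flavonoids gave 10 of 14 higher and 1 lower, median 1.14 (adjusted p = 0.00349, and adjusted p = 0.267 with an estimated correlation). CHS was at 4.85 ± 0.32 and PAP1 at 2.80 ± 0.30. Starch gave 10 of 13 lower and 3 higher, median −0.80 (adjusted p = 0.00769, and adjusted p = 0.208 with an estimated correlation). PHS1 was at −1.79 ± 0.06 and GBSS1 at 2.39 ± 0.34. DREB2A, a regulator of drought and heat genes, rose by 3.46 ± 0.55 and RD29B by 2.32 ± 0.31, while the abscisic acid list was at 0.60 (adjusted p = 0.0789). Ribosomal proteins were at −0.13 (adjusted p = 0.615), and at 0.14 with quantile scaling. RBCS1A fell by 0.45 ± 0.09 but was at 0.30 with quantile scaling. PAD4 (0.25 ± 0.28) and RAB18 (−0.12 ± 0.12) did not pass (RAB18 0.67 with probes averaged), and PR1 was not above background in either group. Of all genes, 59.6% had arrays that did not overlap (2.86% by chance). Scan date as a block gave 14612 genes, slide as a random block 12949, and the scan dates alone 12505 and 12081. All 7 lists called kept their sign within both dates (salicylic acid −0.82 and −1.01).

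**Figure D4:**
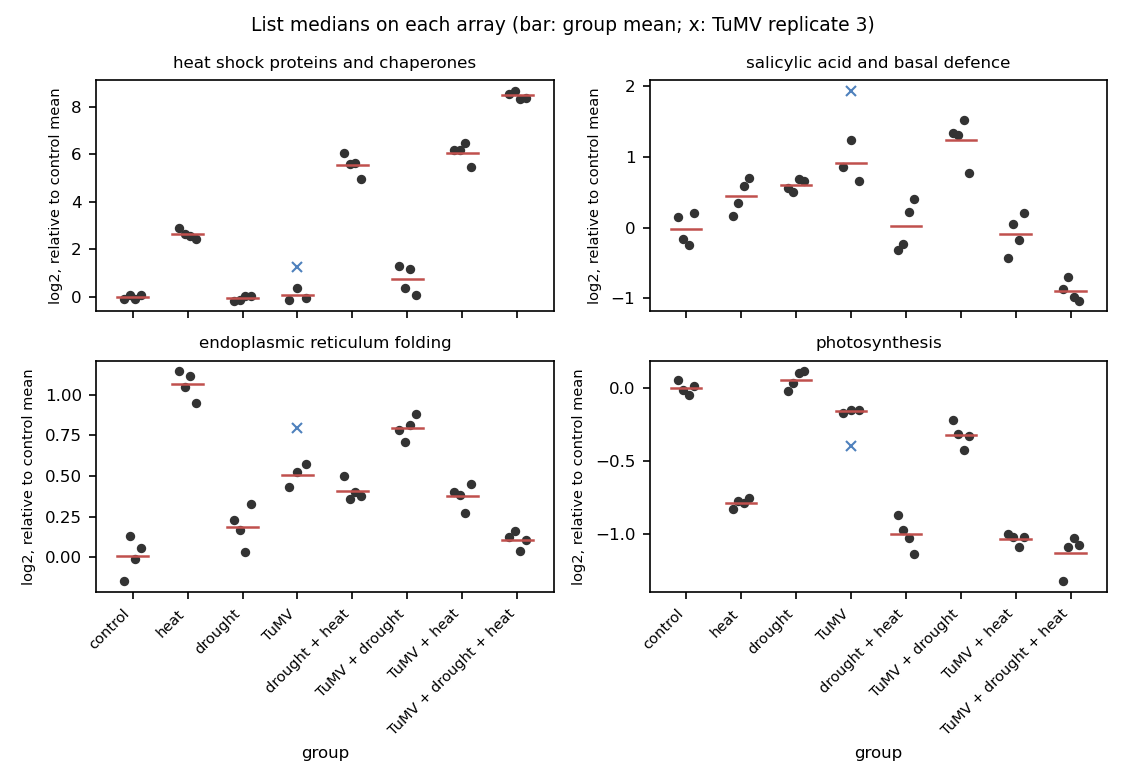
Median log2 level of 4 gene lists in each array relative to the mean of control, by group, with dots for arrays, bars for group means and a cross for TuMV replicate 3, which was left out. The salicylic acid list of that array stood at 1.94, with controls from −0.25 to 0.21.

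TuMV in drought, the difference between infected and uninfected droughted leaves (n = 4 and 4), lowered photosynthesis genes: 40 of 46 fell and 0 rose (41 and 0 adjusted over the list alone), median −0.40 (adjusted p = 1.44e-22). LHCB1.1 was at −1.34 ± 0.12. In endoplasmic reticulum folding, 16 of 16 rose and 0 fell, median 0.66 (adjusted p = 2.67e-14). ERDJ3A was at 1.55 ± 0.27. Jasmonate genes gave 14 of 30 higher and 0 lower (16 and 0 adjusted over the list alone), median 0.88 (adjusted p = 1.26e-06, and adjusted p = 0.339 with an estimated correlation). JAZ10 was at 3.96 ± 0.69. Flavonoids gave 8 of 14 higher and 0 lower (11 and 0 adjusted over the list alone), median 0.68 (adjusted p = 2.78e-06). CHS was at 2.64 ± 0.32. Chaperones gave 10 of 23 higher and 0 lower (12 and 1 adjusted over the list alone), median 0.74 (adjusted p = 4.39e-06, and adjusted p = 0.317 with an estimated correlation). AT5G51440 was at 2.49 ± 0.41. Salicylic acid genes gave 12 of 37 higher and 0 lower (13 and 0 adjusted over the list alone), median 0.71 (adjusted p = 4.91e-05, and adjusted p = 0.489 with an estimated correlation), or 0.61 with 2 members at their bound. Among them were PR2 (2.44 ± 0.54) and PR5 (1.71 ± 0.37). The clock gave 7 of 14 lower and 1 higher (8 and 2 adjusted over the list alone), median −0.34 (adjusted p = 6.41e-04). PRR5 was at −1.18 ± 0.17. TPS04 (AT1G61120), a terpene synthase, rose at least 24.7-fold, and RAP2.6 and CYP82G1 (AT3G25180), of homoterpene synthesis, at least 26.4-fold and at least 19.7-fold. RBL7 was at least 10.2-fold lower, and EXL5 (AT2G17230) fell by 3.15 ± 0.24. RAB18 fell by 0.57 ± 0.12, and RBCS1A by 0.31 ± 0.09. The call for RBCS1A was lost without drought replicate 4 (−0.26), without TuMV with drought replicate 3 (−0.27), without TuMV with drought replicate 4 (−0.24), with normexp, with probes averaged, with only the 2 groups and with quantile scaling (0.05). The total was 4799 genes, and 6148 with scan date as a block, 3256 with slide as a random block, 2881 with only the 2 groups and 3048 and 3058 within the scan dates. All 9 lists called kept their sign within both dates (photosynthesis −0.27 and −0.53).

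TuMV in heat, the difference between infected and uninfected heated leaves, raised chaperones above their level in heat: 22 of 23 rose and 0 fell (23 and 0 adjusted over the list alone), median 2.57 (adjusted p = 2.41e-43). HSP21 (AT4G27670) of the chloroplast rose by 6.17 ± 0.53, HSP17.6II by 5.39 ± 0.47, HSP101 by 2.46 ± 0.33 and HSFA2 by 2.44 ± 0.52. Endoplasmic reticulum folding genes gave 11 of 16 lower and 0 higher, median −0.51 (adjusted p = 3.88e-12). BIP2 was at −0.87 ± 0.11. For photosynthesis, 18 of 46 fell and 0 rose (25 and 0 adjusted over the list alone), median −0.20 (adjusted p = 5.50e-18). LHCB1.1 was at −1.65 ± 0.12. For the clock, 8 of 14 fell and 1 rose (9 and 1 adjusted over the list alone), median −0.40 (adjusted p = 2.54e-05). PRR5 was at −1.23 ± 0.17. Salicylic acid genes gave 12 of 37 lower and 1 higher, median −0.39 (adjusted p = 5.94e-06, and adjusted p = 0.419 with an estimated correlation). Among them were NPR3 (AT5G45110, −1.60 ± 0.24), NIMIN2 (AT3G25882, −1.44 ± 0.28) and WRKY70 (−1.13 ± 0.27). TIR-NBS-LRR genes gave 15 of 65 lower and 2 higher (23 and 6 adjusted over the list alone), median −0.18 (adjusted p = 5.88e-04, and adjusted p = 0.286 with an estimated correlation), lost with normexp. AT1G72900 was at −1.76 ± 0.35. Ribosomal proteins gave 8 of 185 higher and 2 lower (6 and 2 adjusted over the list alone), median 0.13 (adjusted p = 1.33e-06, and adjusted p = 0.440 with an estimated correlation). The call was lost with normexp, where the median was 0.06 and the test against all other genes turned. CBF4 (AT5G51990), CBF1 (AT4G25490) and CBF2 (AT4G25470) fell by 3.95 ± 0.93, 3.73 ± 0.77 and 3.27 ± 0.75. The total was 2214 genes, and 3070 with scan date as a block, 1239 with slide as a random block, 1409 with normexp (median of all genes moved by 0.128), 1289 without TuMV with heat replicate 3, and 732 and 1867 within the scan dates. Quantile scaling gave 1446 higher and 1096 lower genes (56.9% higher) beside 1036 and 1178 (46.8% higher).

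TuMV in drought with heat raised chaperones again: 23 of 23 rose and 0 fell, median 2.23 (adjusted p = 2.52e-27). Examples were HSP70B (AT1G16030, 4.34 ± 0.25), HSP21 (4.57 ± 0.53) and HSP101 (2.11 ± 0.33). Heat shock factors gave 6 of 13 higher and 1 lower (6 and 3 adjusted over the list alone), median 0.20 (adjusted p = 0.0198, and adjusted p = 0.189 with an estimated correlation). HSFA2 was at 3.19 ± 0.52. APX2 (AT3G09640), an ascorbate peroxidase, rose by 3.51 ± 0.30 and AGO2 by 1.33 ± 0.19. Salicylic acid genes gave 20 of 37 lower and 0 higher (21 and 0 adjusted over the list alone), median −0.74 (adjusted p = 1.61e-13, and adjusted p = 0.141 with an estimated correlation). Examples were WRKY40 (AT1G80840, −3.64 ± 0.74), WRKY33 (AT2G38470, −2.77 ± 0.44) and WRKY70 (−2.26 ± 0.27). TIR-NBS-LRR genes gave 31 of 65 lower and 1 higher (32 and 3 adjusted over the list alone), median −0.40 (adjusted p = 2.60e-12). AT5G41740 was at −3.15 ± 0.49. Photosynthesis gave 10 of 46 lower and 0 higher, median −0.09 (adjusted p = 3.50e-04, and adjusted p = 0.531 with an estimated correlation), with medians within the scan dates of −0.22 and 0.02. LHCB1.1 was at −0.74 ± 0.12. Endoplasmic reticulum folding gave 8 of 16 lower and 1 higher (8 and 2 adjusted over the list alone), median −0.26 (adjusted p = 0.0110, and adjusted p = 0.374 with an estimated correlation), ERDJ3A being higher (2.4 ± 0.27). Of guard cell and trichome markers, 3 of 6 fell and 0 rose, median −0.29 (adjusted p = 0.0254, and adjusted p = 0.267 with an estimated correlation), lost with normexp. CBF1, CML38 (AT1G76650), TCH4 (AT5G57560) and ERF11 (AT1G28370) fell by 4.67 ± 0.77, 4.07 ± 0.83, 4.04 ± 0.54 and 3.91 ± 0.61. The total was 3676 genes, and 4693 with scan date as a block, 2440 with slide as a random block, 2300 with only the 2 groups, 1819 with normexp, and 1249 and 3303 within the scan dates.

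Heat and drought together differed from the sum of their single effects for 3032 genes (1427 above and 1605 below the sum). Chaperones stood above it: 21 of 23 stood above and 0 below (22 and 0 adjusted over the list alone), median 3.06 (adjusted p = 1.41e-27). Over the 15 measured in all 4 groups the median was 2.04. HSP101 was at 3.61 ± 0.47. Heat shock factors gave 5 of 13 above and 0 below, median 0.12 (adjusted p = 0.0194, and adjusted p = 0.189 with an estimated correlation), HSFA2 (3.35 ± 0.74) and MBF1C (2.81 ± 0.57) among them. Endoplasmic reticulum folding stood below it: 9 of 16 stood below and 1 above (11 and 2 adjusted over the list alone), median −0.65 (adjusted p = 1.23e-07). BIP2 was at −1.45 ± 0.15. Salicylic acid genes gave 17 of 37 below and 0 above (20 and 0 adjusted over the list alone), median −1.16 (adjusted p = 9.58e-11, and adjusted p = 0.199 with an estimated correlation). Examples were PR2 (−4.06 ± 0.76) and WRKY38 (−3.69 ± 0.33). Ribosomal proteins gave 45 of 185 above and 0 below (61 and 0 adjusted over the list alone), median 0.26 (adjusted p = 5.56e-15, and adjusted p = 0.164 with an estimated correlation). AT2G24110 was at 0.65 ± 0.14. Photosynthesis gave 11 of 46 below and 0 above, median −0.23 (adjusted p = 2.33e-06, and adjusted p = 0.357 with an estimated correlation), lost with quantile scaling. PSAK (AT1G30380) was at −0.60 ± 0.10. The abscisic acid list gave 8 of 39 above and 2 below, median 0.28 (adjusted p = 0.00436, and adjusted p = 0.374 with an estimated correlation). HAI2 (AT1G07430) was at 2.82 ± 0.33. PHI-1 stood 5.11 ± 1.07 below the sum. Scan date as a block gave 4036 genes, slide as a random block 4079, normexp 974, and the scan dates alone 1265 and 1424. All 9 lists called kept their sign within both dates (chaperones 3.49 and 2.91).

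TuMV by drought passed for 668 genes (241 above and 427 below the sum of the single effects). EXO, PHI-1 and TCH4, a xyloglucan endotransglucosylase, stood 5.08 ± 0.72, 5.09 ± 1.11 and 4.27 ± 0.79 below the sum. Photosynthesis gave 3 of 46 below and 0 above (9 and 0 adjusted over the list alone), median −0.22 (adjusted p = 5.67e-10, and adjusted p = 0.194 with an estimated correlation), lost with quantile scaling. TIR-NBS-LRR genes gave 2 of 65 below and 0 above (3 and 0 adjusted over the list alone), median −0.17 (adjusted p = 0.00131, and adjusted p = 0.329 with an estimated correlation). AT3G04210 was at −1.16 ± 0.21. Flavonoids gave 2 of 14 above and 0 below (3 and 0 adjusted over the list alone), median 0.37 (adjusted p = 0.00680, and adjusted p = 0.312 with an estimated correlation). Chalcone isomerase, CHI (AT3G55120), was at 0.80 ± 0.16. None of the 15 genes considered in every contrast passed, the nearest being LHCB1.1 (−0.57 ± 0.18, adjusted p = 0.0951). The total was 1181 with scan date as a block, 550 with slide as a random block, 1069 with replicate number as a block and 224 with normexp (46 above and 178 below, 20.5% above beside 36.1%). It was 414, 417 and 424 without drought replicate 3, TuMV replicate 2 and TuMV replicate 1, and 196 and 642 within the scan dates. All 5 lists called kept their sign within both dates (photosynthesis −0.10 and −0.38).

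TuMV by heat passed for 2535 genes (1095 above and 1440 below the sum). Chaperones stood above it: 19 of 23 stood above and 0 below (20 and 0 adjusted over the list alone), median 2.68 (adjusted p = 5.22e-21). Over the 15 measured in all 4 groups the median was 1.62. HSP101 was at 1.99 ± 0.49. Endoplasmic reticulum folding stood below it: 12 of 16 stood below and 0 above (13 and 0 adjusted over the list alone), median −0.98 (adjusted p = 5.97e-20). BIP2 was at −1.74 ± 0.16. Salicylic acid and basal defence genes gave 21 of 37 below and 0 above (29 and 0 adjusted over the list alone), median −1.29 (adjusted p = 1.15e-19). Examples were WRKY40 (−5.0 ± 1.08), WRKY18 (−4.16 ± 0.70) and WRKY53 (AT4G23810, −3.18 ± 0.65). TIR-NBS-LRR genes gave 22 of 65 below and 1 above (30 and 2 adjusted over the list alone), median −0.48 (adjusted p = 1.14e-10). AT5G41740 was at −3.75 ± 0.72. Jasmonate genes gave 13 of 30 below and 0 above (14 and 0 adjusted over the list alone), median −0.65 (adjusted p = 1.16e-07, and adjusted p = 0.277 with an estimated correlation). Over the 24 measured in all 4 groups the median was −0.47. Examples were JAZ5 (AT1G17380, −4.47 ± 0.79) and, outside the list, CYP94B3 (−7.27 ± 1.79). Ribosomal proteins gave 7 of 185 above and 1 below (1 and 0 adjusted over the list alone), median 0.16 (adjusted p = 2.87e-04, and adjusted p = 0.611 with an estimated correlation). The call was lost with normexp, where the median was 0.09 and the test against all other genes turned. LHCB1.1 stood 0.89 ± 0.18 below the sum. The total was 3449 with scan date as a block, 2192 with slide as a random block, 1106 with normexp (median of all genes moved by 0.135), and 1105 and 1587 within the scan dates. All 8 lists called kept their sign within both dates (salicylic acid −1.46 and −1.09).

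The 3-way interaction passed for 131 genes (2206 at unadjusted p below 0.05). Photosynthesis genes gave 4 of 46 above and 0 below (18 and 0 adjusted over the list alone), median 0.34 (adjusted p = 2.12e-19). The list's medians within the scan dates were 0.08 and 0.66. LHCB1.1 was at 1.48 ± 0.26. The clock gave 0 of 14 above and 0 below (4 and 0 adjusted over the list alone), median 0.32 (adjusted p = 7.43e-05). Chaperones gave 3 of 23 below and 0 above (11 and 1 adjusted over the list alone), median −1.33 (adjusted p = 4.59e-07, and adjusted p = 0.265 with an estimated correlation), and a median of −0.78 over the 15 measured in all 8 groups. Heat shock factors gave 1 of 13 above and 0 below, median 0.47 (adjusted p = 0.0156, and adjusted p = 0.170 with an estimated correlation), lost without TuMV with drought replicate 4 (0.35). HSFA7A was at 2.83 ± 0.49. LHCB1.1 was the only one of the 15 genes considered in every contrast to pass. The total was 243 with scan date as a block, 286 with slide as a random block, 311 with slide as a fixed block and 246 with replicate number as a block. It was 66 with no filter, 20 with normexp (15 above and 5 below, 75% beside 53.4%, the median of all genes moving by −0.165) and at most 167 with 1 array left out. It fell to 64 without TuMV replicate 1 or drought replicate 3, to 67 without drought with heat replicate 3, to 72 without heat replicate 3 and to 74 without control replicate 2. It was 78 without TuMV with heat replicate 2, 79 without triple stress replicate 3, 80 without TuMV replicate 2 and 84 without TuMV with drought replicate 2 or 3. The scan dates alone gave 46 and 110.

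The effect of TuMV was set against itself across backgrounds for the 3295 genes called for TuMV alone. In drought its slope was 0.603 (correlation 0.779), with 87.0% of genes of the same sign, 1650 called the same way and 63 the opposite way. In heat the slope was −0.0564 (correlation −0.109; 57.7% of the same sign, 370 called the same way and 301 the opposite way), and in drought with heat −0.335 (correlation −0.501; 33.8%, 215 and 818). Taken the other way, as the effect of TuMV alone on that within the background for genes called in the background, the slopes were 0.596 over 4799 genes, −0.118 over 2214 and −0.345 over 3676. BIP2 rose by 0.88 ± 0.12 for TuMV alone and 0.83 ± 0.11 in drought and fell by 0.87 ± 0.11 in heat. Drought and TuMV shared 842 genes higher and 720 lower (187 and 198 if independent), with 34 and 11 opposite. Split controls (fewer arrays, no expected count) gave 391 to 458 and 301 to 325. Simulations with no effect (0 shared) cannot test real calls. Heat and drought shared 1121 higher and 1284 lower (698 and 743 if independent, 502 to 786 and 490 to 871 with split controls), with 455 and 433 opposite, and heat and TuMV 973 and 900 (496 and 477; 495 to 654 and 459 to 576), with 252 and 188 opposite. All 3 single stresses raised 488 genes and lowered 449, and all 7 stressed groups raised 292 and lowered 390.

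**Figure D5:**
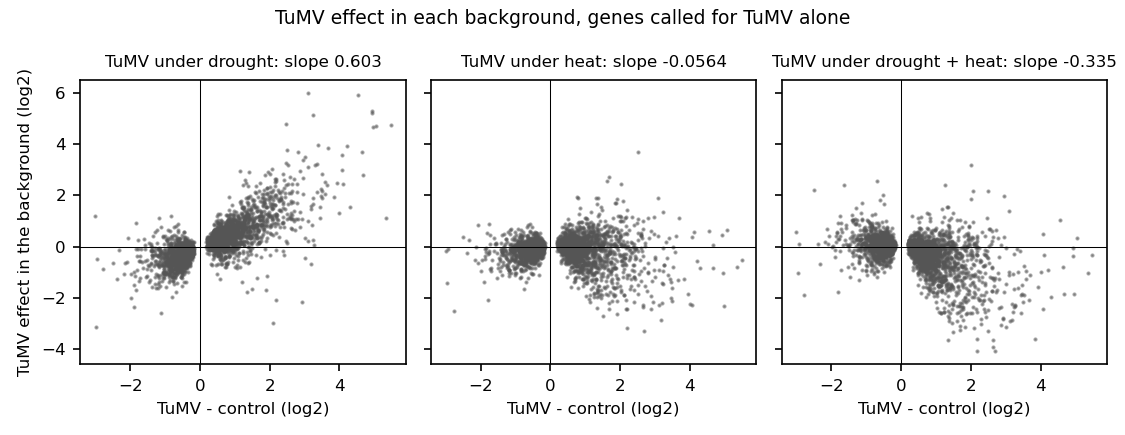
Log2 effect of TuMV in drought, in heat and in drought with heat (vertical axes) against TuMV alone (horizontal axes), with 1 dot for each of the 3295 genes called for TuMV alone. The slopes were 0.603, −0.0564 and −0.335.

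Lists that passed nowhere are given for the single stresses. Senescence genes were at 1.09, 0.07 and 0.03 under heat, drought and TuMV (adjusted p = 0.0714, for heat). Antioxidant genes were at 1.42, 0.07 and 0.01 (adjusted p = 0.206, for heat). Markers of vascular tissue were at −0.23, 0.03 and −0.12 (adjusted p = 0.306, for heat) and of dividing tissue at 0.25, −0.20 and 0.05 (adjusted p = 0.588, for heat). Of 5 flower genes listed, PI (AT5G20240) and SEP3 (AT1G24260) were measured. SEP3, a factor of floral organ identity, rose under heat by 0.94 (adjusted p = 0.00263) and fell under drought (−0.99, adjusted p = 0.00639) and TuMV (−1.14, adjusted p = 0.00518). Control replicate 2 had the highest level of the controls, and without it these values were 1.28, −0.65 (adjusted p = 0.0403) and −0.80. PI was not above background in control.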

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

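Chosen only after the result was seen were the tests of the heat effect slope and of slides, the splits that keep slides whole, scan dates or the other stress or part every pair, and those without group means. The splits of the arrays with free choice and the other tests of the patterns weighed here were set before their values were seen.

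The interactions stood out because effects differed between backgrounds by a direct test, with 3032 genes for heat by drought, 668 for TuMV by drought, 2535 for TuMV by heat and 131 for the 3-way term. Lists that also passed with an estimated correlation were chaperones (median 3.06) and endoplasmic reticulum folding (−0.65) in heat by drought, chaperones (2.68), endoplasmic reticulum folding (−0.98), salicylic acid defence (−1.29) and TIR-NBS-LRR genes (−0.48) in TuMV by heat, and photosynthesis (0.34) and the clock (0.32) in the 3-way term.

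The drop of salicylic acid and basal defence genes below the sum in TuMV by heat (median −1.29) was weighed against 4 technical explanations, the first 3 of which needed a median above −0.65. The values argue against scaling between arrays, the one nearest 0 being −1.08, with normexp (−1.26 with quantile scaling). Scan date gave −1.46 and −1.09, and the members above background in every array −1.28. They also argue against slides, since the 2 slides of a group differed by at most 0.57 in the list's median, less than the interaction on either set of slides (one per date), and the list passed with slide as a random block (−1.29, adjusted p = 3.86e-19). Open are that heat may weaken this response to the virus, a hypothesis found on the same arrays, and that virus amount, not measured here, could differ.

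Chaperones rose more when heat met drought or TuMV than in heat alone. Within the scan dates the lowest of their median interactions was 2.16, with 1.5 as the bound, and members above background in heat differed from heat alone by a median of at least 2.57 (23 members), so neither date nor dim probes account for it. A stronger heat response of all genes would need a slope near the ratio of the list's medians (1.95 under drought, 1.84 under TuMV), but without the list, and relative to heat on itself between the dates, it was 0.969 and 0.845 under drought and 0.699 and 0.626 under TuMV. The 2 slides of a group differed by at most 0.51, less than the interaction on either set of slides (3.49 and 2.91 for heat by drought, 2.16 and 3.07 for TuMV by heat), and the list passed with slide as a random block (adjusted p at most 3.33e-21), which argues against slides. Open is that the combined stress may act on these genes beyond the temperature treatment, or on leaf temperature, not measured here.

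Other splits of the same arrays tested whether chance can be excluded. In the 10 comparisons of 2 groups the real split gave the most genes of 35 (1 of 35 as large): heat 12329 (highest other 2216), drought 4882 (1146), TuMV 3295 (1470), drought with heat 13594 (2995), TuMV with drought 7639 (2164), TuMV with heat 12110 (50), triple stress 13884 (1155), TuMV in drought 4799 (1066), in heat 2214 (10) and in drought with heat 3676 (520). If arrays of both scan dates can change places, chance in placing single arrays is excluded for all but TuMV in heat, but only 18 splits keep the dates balanced, too few for a share under 5% (1 of 18 as large, highest other 1611). Apart from heat the 10 comparisons are between slides, and 3 splits keep slides whole, too few (1 of 3 as large, highest other 2). For TuMV in heat, pairing by number was not shown beyond scan date. If it holds, only 8 splits part every pair, too few (1 of 8 as large, highest other 0). Of 100 free splits for the interactions, 7 were as large for heat by drought (3032, highest other 11255), 6 for TuMV by heat (2535, 10317), 3 for TuMV by drought (668, 4185) and 2 for the 3-way term (131, 5760). The highest counts point to a structure of the samples, which the treatments largely account for in these free splits. Those as large had at least 71.4% of the arrays of 1 stress on one side of the contrast (median split 62.5%). With each group's mean removed the free splits gave at most 1064, 33, 10 and 0 genes. In the same order, of 100 splits within the scan dates 8, 11, 3 and 2 were as large (highest others 11499, 9876, 4103 and 2606), of 100 that keep the other stress 1, 1, 4 and 2 (1121, 1526, 3644 and 1347), and of 100 that keep both 1, 1, 5 and 5 (2390, 1475, 2630 and 1044). All these splits move at least 1 single effect, so they cannot decide, and chance stays open for every interaction. Those keeping the other stress were chosen after free ones failed to exclude it. No splits for interactions regarded slides or replicate numbers.

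In 13 of 296 groups of arrays 1 array stood far from the others, where chance alone gives about 1 in 20 groups (14.8). The 75th percentile of signal was 1495 in TuMV with drought replicate 1 (others 1704 to 1721), and 76.4% of probes were above background in triple stress replicate 2 (others 70.8 to 71.6%). Saturated probes were 0.00917% in drought with heat replicate 2 and 0.00229% in TuMV with heat replicate 2, and 0 in the others of those groups. Control replicate 3 had a median correlation of 0.989 with its group (others 0.988), and control replicate 2 a flower marker level of 0.95 (others −0.38 to −0.22). The guard cell and trichome list was at 0.0972 in heat replicate 4 (others −0.07 to −0.06), and the jasmonate list at 0.99 in both heat replicate 3 (others 0.75 to 0.78) and drought replicate 4 (others 0.28 to 0.40). HSFA2 was at −0.91 in TuMV with drought replicate 4 (others −0.41 to −0.37), AT1G53540 at −8.22 in drought replicate 1 (others −7.72 to −7.67), RAB18 at 3.35 in triple stress replicate 1 (others 3.66 to 3.72) and PR1 at −6.00 in drought replicate 2 (others −8.13 to −7.86).

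TuMV replicate 3, left out of the comparisons, carried signals above the control arrays. Its salicylic acid list was at 1.94 (controls −0.25 to 0.21), its jasmonate list at 0.44 (−0.29 to 0.30) and its endoplasmic reticulum list at 0.80 (−0.15 to 0.13). PR1 was at −0.41 (controls −7.29 to −6.67), PR2 at 4.36 (−1.53 to −0.17) and PR5 at 4.66 (1.22 to 1.63). Across genes its SD from the group mean was 0.428 for TuMV, 0.424 for TuMV with drought, 0.619 for drought, 0.707 for control and at least 0.827 for the heated groups. Genes are not independent replicates.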

How the results depend on the processing

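No test in this part was chosen after the result was seen. Of 488 alternative values of the gene counts, 421 stayed within 1.5 times the reported count, and the count of gene lists that passed (115) did so in all 43 of its alternatives (113 to 123 with 1 array left out). Quantile scaling, the deposited values, the stricter filter, the mean of probes and TuMV replicate 3 moved none of the 21 counts by more than 1.5 times. Of 6573 alternative list results 6322 kept their side of the threshold, 78 lost it, 166 gained it and 7 turned direction. Of 14579 for named genes these numbers were 13775, 707, 84 and 13. All 12 alternative slopes of the TuMV effect kept their direction. Within the scan dates 115 and 113 of the 115 lists that passed kept their sign, the exceptions on the second date being photosynthesis for TuMV in drought with heat (0.02) and abscisic acid genes for TuMV in heat (0.01).

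Normexp gave fewer genes: 3654 higher for heat, 1045 higher and 902 lower for drought, 738 and 602 for TuMV, 1777 and 2077 for TuMV with drought, 1882, 1409 and 1819 for TuMV in drought, in heat and in drought with heat, and 974, 224, 1106 and 20 for heat by drought, TuMV by drought, TuMV by heat and the 3-way term (the cause was not tested). With no filter, more genes tested gave 8778 lower for TuMV with heat, while the 3-way term fell to 66 genes (the cause was not tested). Each probe by itself, with more tests, gave 3831 lower for drought, 10432 for drought with heat and 8838 for TuMV with heat. Slide as a random block gave 1659 lower for drought, 1080 lower for TuMV, 1239 and 2440 for TuMV in heat and in drought with heat, and 286 for the 3-way term, which slide as a fixed block put at 311 (the cause was not tested). Scan date as a block gave 1181 genes for TuMV by drought and 243 for the 3-way term, and replicate number as a block 1069 and 246 and no other such move (the cause was not tested). Only the groups compared, fewer arrays, gave 1445 lower for drought, 2881 for TuMV in drought and 2300 for TuMV in drought with heat.

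Asking for at least 2-fold leaves fewer genes by construction: 2081 higher and 1063 lower for heat, 434 and 139 for drought, 641 and 149 for TuMV, 2420 and 1811 for drought with heat, 1139 and 368 for TuMV with drought, 1822 and 1221 for TuMV with heat, 2301 and 2085 for the triple stress, 799, 461 and 828 for TuMV in drought, in heat and in drought with heat, and 856, 279 and 1088 for heat by drought, TuMV by drought and TuMV by heat. With 1 array left out, so fewer arrays, the ranges were 1024 to 1472 lower for TuMV (lowest without TuMV replicate 2), 1289 to 2021 for TuMV in heat (lowest without TuMV with heat replicate 3), 414 to 818 for TuMV by drought (lowest without drought replicate 3) and 64 to 167 for the 3-way term (lowest without TuMV replicate 1 or drought replicate 3).

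Directions turned in 20 results, and the cause was not tested. With quantile scaling ribosomal proteins were at 0.0431 in heat, 0.24 in TuMV with heat and 0.14 in the triple stress, aquaporins at 0.40 in TuMV with heat, RAB18 at 0.39 in drought with heat and RBCS1A at 0.15, 0.26, 0.16, 0.30 and 0.0503 in heat, drought with heat, TuMV with heat, the triple stress and TuMV in drought. With normexp the test of ribosomal proteins turned at medians of 0.0586, 0.0933 and 0.0757 for TuMV in heat, TuMV by heat and the 3-way term, and 4 gene values turned: AT1G63857 at 0.23 and 0.29 for TuMV in heat and TuMV by heat, AT2G24730 at 0.37 for TuMV in heat and WRKY62 (AT5G01900) at 0.0401 for heat by drought. With probes averaged RAB18 was at 0.38 in drought, 0.99 in drought with heat and 0.67 in the triple stress. Signal over background limits genes such as PR1, for which only a bound on the fold can be given.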

Other observations

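Most measured genes of endoplasmic reticulum bodies, compartments that hold beta-glucosidases, rose in the heated groups, a list written after the rise of PYK10 was seen. Of 15 listed 12 were measured, and 9 rose and 0 fell under heat (median 1.78, or 1.75 with 1 member at its bound and 1 dim in both groups left out), where 6215 of all 20875 genes rose. Against other genes the list passed in all 4 heated groups with a preset correlation (adjusted p at most 0.0016), but not with an estimated correlation (adjusted p = 0.337). NAI1 (AT2G22770), a regulator needed to form the bodies, rose by 2.75 and NAI2 (AT3G15950), a component of them, by 3.05. JAL22 (AT2G39310) rose at least 3.36-fold, GLL23 (AT1G54010) by 3.49 and PBP1 (AT3G16420) by 1.88. The medians, with members at their bound in parentheses, were 1.68 (1.44) in drought with heat, where 11 of 12 rose and 1 fell, 1.74 (1.85) in TuMV with heat, where 9 rose and 0 fell, and 2.11 (1.66) in the triple stress, where 11 rose and 1 fell. The one that fell was MVP1 (AT1G54030, −0.70 and −0.47), and MVP1, TSA1 (AT1G52410) and JAL33 (AT3G16450) did not pass under heat. PYK10 itself stood at a mean level of −7.17 in control and 1.17 in heat, and DR4 at −7.45 and −1.07.

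Chosen only after the result was seen were the test of the other PYK10 probes and that of the list against other genes; the tests of root markers and of the median of these bodies were set before their values were seen. PYK10 and DR4 are known from roots. Of 28 root markers the 17 above background had a median heat change of 0.0544 (5 rose, 2 fell), under the bound of 1. Most were measured in control too, so a trace of root stays open. The 6 other passing PYK10 probes rose, but dim flat ones cannot pass, so binding of another transcript stays open. The rise is consistent with a rise of the genes of endoplasmic reticulum bodies (median 1.78, with 1 as the least needed), not told from other genes with an estimated correlation, and remains a hypothesis found and tested on the same arrays.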
